A study of Mus musculus with 6 samples.

How the data were processed

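RNA sequencing was done on 6 libraries of mouse splenic B cells, 3 of a control group (CD19-Cre) and 3 of a RELA-deleted group (floxed Rela with CD19-Cre), all cultured for 6 h with anti-CD40 and anti-IgM. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected, libraries were made with the Illumina TruSeq RNA kit and 100-base reads were produced on a HiSeq2000. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.4 and Cufflinks 2.0.2 were used with the mouse genome build mm9, with no roles given. The tool that counted reads per gene, its annotation and its strand setting are not given in the sources used here, so reads of overlapping genes and of genes on opposite strands cannot be told apart, and near-identical paralogs may share or split reads.

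The authors deposited 1 table of read counts per gene symbol, with 23284 symbols and 1 column for each of the 6 samples. The values were whole numbers whose totals differed between libraries, from 19456048 to 22249494, and they had not been normalized. Among the symbols, 25 had been turned into dates by a spreadsheet. Of these, 16 were among the tested genes and 2 were past the threshold, and none is named. Counts were 0 in all libraries for 6806 symbols. The 10 most abundant genes took 3.73% to 3.99% of the counts of a library. The only reference annotation at hand was of a later mouse genome build than mm9, so no gene positions are given.

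The design planned before the data were examined assumed FPKM values and named edgeR as the test in case the table held counts. It held counts, and edgeR was used. Genes were kept by filterByExpr with its minimum count of 10, which left 11898 genes. Libraries were scaled with TMM factors (0.995 to 1.004), and genes were tested with glmQLFit and glmQLFTest (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and group as the only term. The biological coefficient of variation was 3.05%. Fold changes used a prior count of 0.125. Standard errors are approximate: they were taken as the size of the log2 fold change divided by the square root of the F statistic. Means and SDs are of TMM-scaled CPM over n = 3 libraries per group.

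Named genes were chosen by a rule fixed before the data were examined. It took Rela, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose 3 RELA-deleted libraries all lay beyond the 3 control libraries, and from each of 25 gene lists the up to 4 measured members with the smallest p. Genes outside the rule were named after their values were seen. The lists were NF-kB pathway components, NF-kB target genes, B-cell activation and costimulation, B-cell receptor signalling, plasma cell programme, germinal centre and B-cell identity, apoptosis regulators, cell cycle and DNA replication, glycolysis, mitochondrial respiration, ribosome biogenesis and MYC targets, cholesterol and lipid synthesis, interferon response, antigen presentation, cytokines, chemokines and receptors, immediate early and stress genes, marginal zone and B1 markers, follicular and immature B-cell markers, T and NK cell markers, monocyte, macrophage and dendritic markers, neutrophil and granulocyte markers, erythroid and platelet markers, stromal and endothelial markers, sex-linked genes and genes flanking Rela. Some genes stand in more than 1 list. The 22 lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over these lists. With camera 12 lists passed, 5 higher and 7 lower, and 2 of them passed with an estimated correlation, the interferon response and antigen presentation. With fry 14 lists passed.

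On counts simulated from the means and library sizes of this comparison (11817 genes run, 50 genes changed at each fold and a list of 38 further genes lowered by 0.5 on the log2 scale), the test recovered 24% of genes changed 1.1-fold, 74% at 1.25-fold, 86% at 1.5-fold and 90% at 2-fold, with 5 false calls among 178 that include 36 genes of the list. Of the single genes, over all folds, 12 of 40 under 5 CPM and 125 of 160 at 5 CPM or more were recovered, so changes in low genes are found less often. The simulation changed far fewer genes than passed in the data, which makes the adjusted threshold stricter. It drew each gene independently, with a spread set by expression level alone. The shares recovered and the false calls therefore need not hold for these libraries. Ratios of summed counts with 95% exact binomial intervals were added for genes of the largest changes with 3 counts or fewer in a library, and such intervals and the limit of 3 counts at a count of 0 cover counting error only. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom of 1.75 to 3.83 over genes, against 9.23 to 13.5 between groups), so none was treated as a duplicate. The labels name no batch, lane or day of preparation for a library.

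Alternatives planned before the data were examined were limma on log2(CPM + 0.1) and on log2(CPM + 0.5), no filter on low counts, a filter of at least 5 CPM on average, quantile normalization with limma voom, median-ratio size factors, the replicate number as a block, no abundance trend, robust moderation, sample weights with limma voom, DESeq2 1.42.0, an adjusted p under 0.1, camera with an estimated correlation, fry, and leaving out each library in turn. Limma on log2(CPM + 1) and scaling by total count alone were added after seeing the data. The closing section gives their effect.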

Results

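Messenger RNA was measured in mouse splenic B cells with and without RELA (p65), a transactivating NF-kB subunit of the canonical pathway. B cells were purified with magnetic beads from spleens of mice aged 12 weeks and cultured for 6 h with antibodies against CD40, a costimulatory receptor, and against IgM, the surface form of the B-cell receptor. In the RELA-deleted group both Rela alleles were floxed and Cre recombinase was expressed from the B-lineage gene Cd19, and the control group consisted of littermates with CD19-Cre alone. Each group held 3 libraries. The deposited values were read counts per gene symbol, with totals of 20152759, 20574496 and 19581446 in control replicates 1 to 3 and of 22017908, 22249494 and 19456048 in RELA-deleted replicates 1 to 3. The labels do not say whether each library came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical. The comparison asks which transcripts differ when RELA is missing from B cells stimulated through both receptors.

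Rela itself was reduced to 18.9% of its control level, with an SD of 1.58 percentage points propagated from the SDs of both groups (n = 3 each). It stood at 203 ± 10.3 CPM (counts scaled to a common library size) in the control libraries and at 38.3 ± 2.57 CPM in the RELA-deleted libraries (SD, n = 3 each), from 4274, 4206 and 3751 counts against 870, 897 and 691 counts. The log2 fold change was -2.40 with a standard error of 0.05 (adjusted p = 1.21e-15, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A two-sided exact permutation test of the group means gave p = 0.1, the smallest value that 3 libraries against 3 can give. The counts cover Rela as a whole, and the labels do not name the floxed exons, so the remaining reads do not measure intact Rela.

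Of 11898 genes tested, 890 rose and 1096 fell in the RELA-deleted libraries at an adjusted p under 0.05 (edgeR's quasi-likelihood test). Most of these changes were small: 80.1% lay under 0.5 on the log2 scale in either direction, and the median size was 0.23. At least 2-fold changes were found in 41 genes that rose and 72 genes that fell. In 1952 of the 1986 changed genes the 3 RELA-deleted libraries all lay beyond the 3 control libraries. That held for 32.9% of all tested genes, where chance gives 10%. The number of genes that rose depended on the test and on single libraries, being 575 with DESeq2, 550 without RELA-deleted replicate 1 and 543 without RELA-deleted replicate 2.

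**Figure D1:**
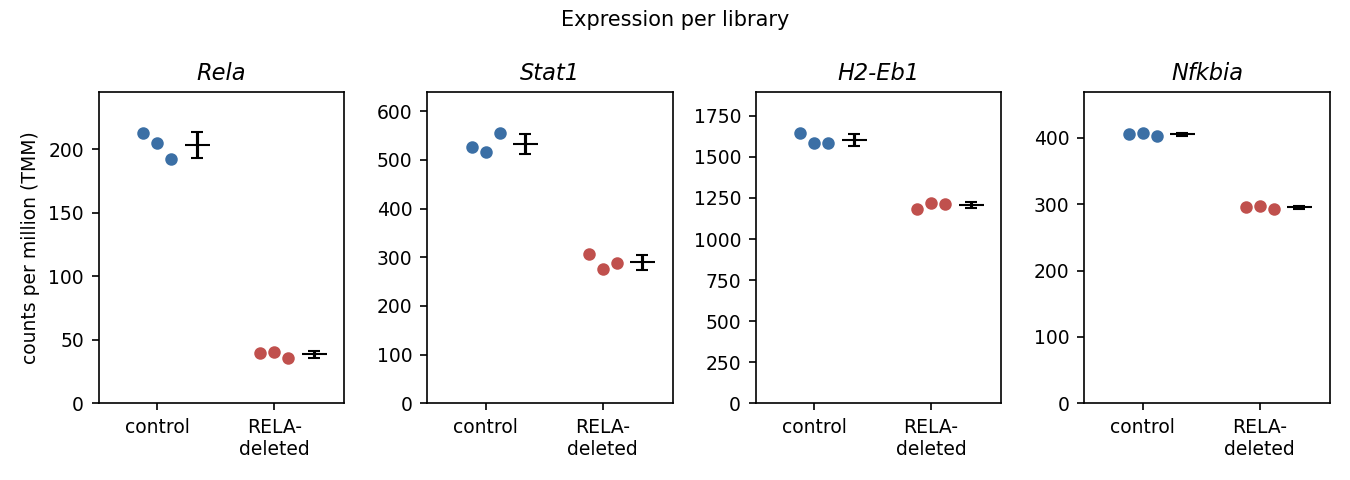
CPM (TMM-scaled, linear axis from 0) of Rela, Stat1, H2-Eb1 and Nfkbia in each library, with points for the 3 libraries of each group and bars for the mean and SD. Rela fell from 203 to 38.3 CPM, and in each of the 4 genes all RELA-deleted libraries lie below all control libraries.

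The genes with the largest rises were nearly all expressed at low levels. Ocln, which encodes the tight-junction protein occludin, rose from 0.334 ± 0.081 to 2.36 ± 0.194 CPM (log2 fold change 2.80, SE 0.26). Penk, the precursor of enkephalin peptides, rose by 2.31 (SE 0.35), and the transcription factor gene Hnf1b by 2.18 (SE 0.24). Lag3, which encodes an inhibitory receptor that binds MHC class II, was the most abundant of this group and rose from 3.29 ± 0.274 to 14.6 ± 0.191 CPM (2.14, SE 0.10). Il6, a cytokine, rose by 1.58 (SE 0.25), from 11 to 13 counts in the control libraries to 34 to 41 counts. The other genes of this group were the transcription factor gene Sox5 (2.65), the meiotic gene Syce1 (2.02), the uncharacterised 4931408D14Rik (1.91), the receptor kinase gene Tyro3 (1.77), the neutrophil surface marker Cd177 (1.75), the T-cell coreceptor Cd4 (1.71) and the cytotoxic granule protease Gzma (1.64). Markers of T and NK cells, a list that holds Cd4 and Gzma themselves, had a median log2 change of 0.41. Markers of neutrophils, a list without Cd177, had a median of 0.62, the same direction as Cd177. Several of these genes had 3 counts or fewer in a control library, where counting error dominates. Summed over each group, the ratio of CPM was 6.62 for Sox5 (95% exact binomial interval 2.80 to 19.1), 5.09 for Penk (2.96 to 9.30), 3.85 for 4931408D14Rik (2.16 to 7.29), 3.49 for Tyro3 (2.08 to 6.13), 3.35 for Cd4 (1.78 to 6.76) and 3.19 for Gzma (1.801 to 5.98), intervals that cover counting error only. The call on Cd4 was lost without control replicate 1 (adjusted p = 0.0569), control replicate 2 (0.0706) or RELA-deleted replicate 2 (0.0963) and with DESeq2 (0.0677), and that on Gzma without RELA-deleted replicate 1 (0.0869).

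Among the largest falls, several genes were well expressed. Hspg2, which encodes the basement-membrane proteoglycan perlecan, fell from 37.7 ± 1.8 to 13.1 ± 0.715 CPM (log2 fold change -1.53, SE 0.06). Rtp4 fell from 22.8 ± 1.23 to 8.36 ± 0.461 CPM (-1.44, SE 0.08) and Ifit3 from 17.0 ± 2.51 to 6.17 ± 0.786 CPM (-1.46, SE 0.12), both of them genes induced by interferon. The transcript 9030617O03Rik fell by 1.44 on the log2 scale (SE 0.10). Cxcr7, an atypical chemokine receptor (-1.43), Zfp365 (-1.69), the matrix protein gene Smoc1 (-1.55) and Gatm, an enzyme of creatine synthesis (-1.45), fell from lower levels. Capn11, a calpain protease gene, had the largest fall, from 25 to 34 counts to 2 to 6 counts per library (-3.14, SE 0.38). Its control-to-deleted ratio of summed counts, scaled by library totals, was 9.09 (95% exact binomial interval 4.71 to 19.6). Evc (-1.49) and the germinal centre gene Gcet2 (-1.47) also passed the threshold, but Evc lost its call with DESeq2 (adjusted p = 0.0553), and Gcet2 lost it with DESeq2 (0.132), without control replicate 1 (0.0656) and without RELA-deleted replicate 1 (0.0681).

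**Figure D2:**
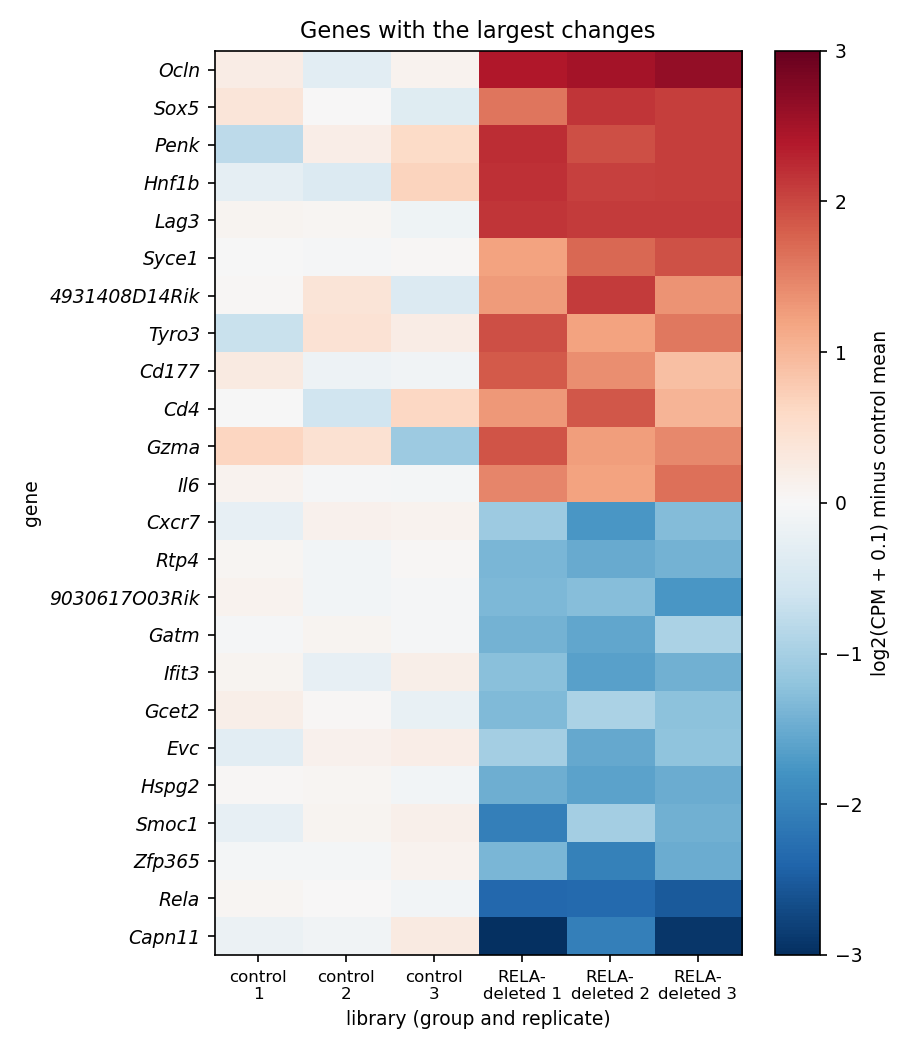
Heat map of the 12 genes with the largest rise and the 12 with the largest fall (rows) in the 6 libraries (columns), coloured by log2(CPM + 0.1) minus the mean of the 3 control libraries. In each gene the 3 RELA-deleted libraries lie on 1 side of the 3 control libraries, a condition these genes were chosen by.

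Interferon response genes were lower in RELA-deleted cells almost throughout the list. Of 38 measured members, 36 fell and 0 rose with edgeR and with DESeq2, and 38 fell and 0 rose when adjusted over the list alone or at an unadjusted p under 0.05. The median log2 change was -1.05, a fall of 2.08-fold. Stat1, the transcription factor that carries signals from interferon receptors, fell from 533 ± 20.7 to 290 ± 15.6 CPM (-0.88, SE 0.04). The nucleic acid sensor Zbp1 fell by 1.33 (SE 0.06), the double-stranded RNA-activated kinase gene Eif2ak2 by 0.95 (SE 0.04) and the nuclear body gene Sp100 by 0.71 (SE 0.03) on the log2 scale. Irf7, Isg15, Mx1 and Cxcl10, named after their values were seen, changed by -1.30, -1.19, -1.34 and -1.31. Irf1 (-0.11) and Gbp2 (-0.19) were the members that did not pass over all genes. The list was lower than other genes with camera (adjusted p = 9.07e-142) and also with an estimated correlation (adjusted p = 0.0169). Members of the Ifit, Oas, Gbp and Trim30 families share sequence, and reads may be divided between them.

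Antigen presentation genes were lower as well, by smaller amounts. Of 29 measured members, 24 fell, 1 rose and 4 did not pass, with a median log2 change of -0.32. Adjusted over the list alone, 25 fell and 1 rose. Of the MHC class II route, H2-Eb1 fell from 1605 ± 37.9 to 1206 ± 17.7 CPM (-0.41, SE 0.03), and the lysosomal thiol reductase gene Ifi30 fell by 0.51 (SE 0.03). Of the class I route, the peptide transporter gene Tap1 fell by 0.46 (SE 0.03) and tapasin, Tapbp, by 0.43 (SE 0.03). The rise was in H2-Ob (0.10), and the members that did not pass were Tapbpl (-0.10), Erap1 (-0.06), Cd1d1 (0.19) and H2-M3 (-0.06), all named because they were the exceptions. The camera adjusted p was 1.73e-32, and it was 0.00816 with an estimated correlation. No member rose without control replicate 1, RELA-deleted replicate 2 or RELA-deleted replicate 3 (count 0), and reads of H2 genes may be divided between near-identical members.

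Components of the NF-kB pathway other than Rela tended to be lower. Of 33 measured members, 18 fell and 2 rose, with a median log2 change of -0.11, and 19 fell and 2 rose when adjusted over the list alone. The inhibitor gene Nfkbia fell from 406 ± 2.32 to 295 ± 1.99 CPM (-0.46, SE 0.03). Relb and Nfkb2, the subunits of the non-canonical pathway, fell by 0.54 (SE 0.03) and 0.35 (SE 0.03), and the deubiquitinase gene Tnfaip3 (A20) by 0.32 (SE 0.03). The subunit genes Rel (-0.09, adjusted p = 0.0206) and Nfkb1 (-0.01, adjusted p = 0.872, edgeR's quasi-likelihood test for both) were named after their values were seen. Nfkbiz (0.37) and Traf6 (0.13) were the members that rose, and the rises numbered 1 without RELA-deleted replicate 1. The list was lower with camera (adjusted p = 1.68e-08) but not with an estimated correlation (adjusted p = 0.107).

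NF-kB target genes, a list that shares 12 members with the components and 12 with the cytokines, went both ways. Of 51 measured members, 23 fell and 13 rose, with a median log2 change of -0.09, and 23 fell and 16 rose when adjusted over the list alone. Marcksl1, which encodes a substrate of protein kinase C, fell from 254 ± 11.1 to 127 ± 1.01 CPM (SE 0.03 on the log2 scale), the adhesion molecule gene Icam1 from 161 ± 2.58 to 102 ± 3.91 CPM (-0.66, SE 0.03) and lymphotoxin beta, Ltb, by 0.70 (SE 0.04) on the log2 scale. Members that rose included the survival gene Bcl2l1 (0.61), Il6 (1.58) and Irf4 (0.21). The chemokine genes Ccl4 (0.75) and Ccl3 (0.57), named after their values were seen, rose too. The list was lower with camera (adjusted p = 5.22e-06), and the call was lost with an estimated correlation (adjusted p = 0.0753). Bcl2a1 paralogs in this list and among the apoptosis regulators are nearly identical, and their counts are uncertain.

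Genes of B-cell activation and costimulation did not move together past the test of the list (camera adjusted p = 0.121). Of 28 measured members, 10 fell and 6 rose, or 11 and 6 when adjusted over the list alone, with a median log2 change of -0.06. Tnfrsf9, the costimulatory receptor 4-1BB, fell from 16.4 ± 0.496 to 8.23 ± 0.886 CPM (-0.99, SE 0.08). Il2ra, the alpha chain of the interleukin-2 receptor, rose from 258 ± 3.1 to 346 ± 11.3 CPM (0.43, SE 0.03), and Icosl, the ligand of ICOS, rose by 0.40 (SE 0.04). By fry, which asks whether members move on balance one way, the list was lower (adjusted p = 0.00493). Genes of B-cell receptor signalling were likewise mixed: 10 of 30 rose and 6 fell, or 11 and 9 adjusted over the list alone, with a median of -0.01 and a mean of 0.01 (camera adjusted p = 0.521). The adaptor gene Bank1 rose by 0.55 (SE 0.04) and the calcium-dependent transcription factor gene Nfatc1 by 0.23 (SE 0.03), while the adaptor Pik3ap1 and the phosphatase Inpp5d fell by 0.27 (SE 0.03) and 0.24 (SE 0.03) on the log2 scale.

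Cytokine, chemokine and receptor genes split between rises and falls. Of 40 measured members, 11 rose and 13 fell, or 12 and 13 when adjusted over the list alone, with a median log2 change of -0.00 (camera adjusted p = 0.242, fry adjusted p = 0.0319 for a fall). Csf1, the growth factor of macrophages, fell from 36.4 ± 0.78 to 16.7 ± 1.02 CPM (-1.12, SE 0.06). The chemokine receptor gene Ccr6 fell from 515 ± 5.38 to 376 ± 8.5 CPM (-0.45, SE 0.03) and Il16 fell by 0.35 (SE 0.03). Il1b (0.62), Ccl3 and Ccl4 rose, and Il1b was named after its value was seen. The neutrophil markers, with a median of 0.62, moved in the same direction as these cytokines.

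Plasma cell genes were mostly lower where they changed. Of 21 measured members, 8 fell and 1 rose, with a median log2 change of -0.09, and 8 fell and 4 rose when adjusted over the list alone. The median ranged from -0.15 to -0.04 with 1 library left out. The J chain gene Igj, whose product joins IgM into polymers, fell from 129 ± 16.5 to 59.3 ± 0.623 CPM (-1.12, SE 0.06). Xbp1, a transcription factor of the secretory programme, fell by 0.28 (SE 0.03) and the endoplasmic reticulum chaperone gene Hspa5 by 0.22 (SE 0.03), while Irf4 was the member that rose. Prdm1, which encodes the plasma cell regulator BLIMP-1 and was named after its value was seen, changed by -0.31. The list was lower with camera (adjusted p = 0.0191), and the call was lost with an estimated correlation (adjusted p = 0.124) and with limma on log2(CPM + 1) (0.101), log2(CPM + 0.5) (0.0994) or log2(CPM + 0.1) (0.0958). Without control replicate 1 or RELA-deleted replicate 1 the falls numbered 5, and the rises numbered 2 with total count scaling, with no abundance trend and with limma voom under quantile normalization or sample weights.

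Germinal centre and B-cell identity genes showed no shift as a list (camera adjusted p = 0.492). Of 27 measured members, 9 fell and 5 rose, over all genes and adjusted over the list alone, with a median of -0.00 and a mean of -0.18. With a filter of at least 5 CPM, 5 fell and 5 rose of 23 measured. Basp1 fell by 0.54 (SE 0.04) and Ciita, the class II transactivator, by 0.32 (SE 0.03) on the log2 scale. The B-cell transcription factor genes Pou2f2 and Irf8 rose by 0.38 (SE 0.04) and 0.23 (SE 0.03). Bcl6 (0.29), Id3 (0.37) and Cd22 (0.23) were the other members that rose. Aicda, which encodes the deaminase of antibody diversification and was named after its value was seen, fell from 1.40 ± 0.0469 to 0.601 ± 0.182 CPM.

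Apoptosis regulators changed in genes of opposite function. Of 33 measured members, 15 fell and 3 rose, or 16 and 4 when adjusted over the list alone, with a median log2 change of -0.11. The anti-apoptotic gene Bcl2l1 (BCL-XL) rose from 106 ± 4.28 to 161 ± 4.24 CPM (0.61, SE 0.04). The death receptor gene Tnfrsf10b fell from 12.8 ± 0.565 to 5.10 ± 0.372 CPM (-1.33, SE 0.09), the pro-apoptotic gene Bbc3 (PUMA) by 0.74 (SE 0.06) and the cell cycle inhibitor gene Cdkn1a (p21) by 0.66 (SE 0.06) on the log2 scale. Bcl2l11 (0.12), which is pro-apoptotic, and Bcl2a1d (0.27), which is anti-apoptotic, were the other rises, and the anti-apoptotic gene Bcl2, named after its value was seen, was among the falls (-0.18). The list was lower with camera (adjusted p = 3.10e-04), and the call was lost with an estimated correlation (adjusted p = 0.0607). The rises numbered 5 without control replicate 3.

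Cell cycle and DNA replication genes changed in few members. Of 47 measured, 8 fell and 4 rose, or 10 and 4 when adjusted over the list alone, with a median log2 change of -0.08. The median ranged from -0.11 without control replicate 1 to -0.04 without control replicate 3. The largest fall was in the inhibitor gene Cdkn1a (-0.66, SE 0.06), which also stands among the apoptosis regulators and acts against the cell cycle. The proliferation marker Mki67 fell from 59.3 ± 0.411 to 41.5 ± 1.76 CPM (-0.51, SE 0.04), topoisomerase Top2a by 0.47 (SE 0.05) and thymidine kinase Tk1 by 0.37 (SE 0.05) on the log2 scale. The replication licensing genes Mcm7 (0.14), Mcm2 (0.13), Mcm5 (0.12) and Cdt1 (0.12) rose. These rises were reduced to 1 without control replicate 2 or RELA-deleted replicate 2 and with DESeq2, and to 2 without RELA-deleted replicate 1. The camera adjusted p was 0.0341, and the call was lost with an estimated correlation (adjusted p = 0.224), without control replicate 3 (0.131) and with a filter of at least 5 CPM (0.053).

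Metabolic and growth lists moved by small amounts. Ribosome biogenesis and MYC target genes had 9 of 39 members that rose and 1 that fell, or 10 and 1 adjusted over the list alone, with a median log2 change of 0.05. Myc rose by 0.20 (SE 0.03), the ribosome assembly genes Ppan and Rrp9 by 0.14 (SE 0.03) and 0.12 (SE 0.03), and the nucleotide kinase gene Nme1 fell by 0.17 (SE 0.04). Rrp9 lost its call without RELA-deleted replicate 1 (adjusted p = 0.0549). The rises numbered 5 without control replicate 1, 4 without control replicate 2 or RELA-deleted replicate 2, and 3 without RELA-deleted replicate 1 or RELA-deleted replicate 3. More rises were found without control replicate 3 (13) and with sample weights in limma voom (12). As a list they were higher with camera (adjusted p = 0.0117), which became 0.0655 without control replicate 2, while the adjusted p was 0.326 with an estimated correlation.

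Cholesterol and lipid synthesis genes had 10 of 28 members that rose and 4 that fell, or 12 and 4 adjusted over the list alone, with a median log2 change of 0.07. Dhcr24, an enzyme of cholesterol synthesis, rose by 0.19 (SE 0.03), the LDL receptor gene Ldlr by 0.16 (SE 0.03) and the cholesterol exporter gene Abca1 by 0.15 (SE 0.03). The desaturase gene Scd2 fell by 0.21 (SE 0.03), with Abcg1 (-0.38), Mvd (-0.13) and Srebf1 (-0.11) as the other falls. The camera adjusted p was 0.0257, and the call was lost without control replicate 2 (0.067), while the adjusted p was 0.233 with an estimated correlation. Without RELA-deleted replicate 1 there were 4 rises and 1 fall, and without RELA-deleted replicate 2 there were 6 rises and 2 falls.

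Glycolysis genes showed no shift as a list (camera adjusted p = 0.981, median -0.01, mean 0.03), with 2 of 22 members rising and 2 falling, over all genes and over the list alone. The lactate transporter genes Slc16a1 (0.24, SE 0.04) and Slc16a3 (0.50, SE 0.16) rose, and the phosphofructokinase gene Pfkp (-0.15, SE 0.03) and the regulatory kinase gene Pfkfb3 (-0.16, SE 0.04) fell. Slc16a3 lost its call in 5 of the 6 leave-one-out fits, all but that without RELA-deleted replicate 3, with adjusted p up to 0.198, and with DESeq2 (0.211), and 1 member of the list rose with a filter of at least 5 CPM. Pfkfb3 lost it without control replicate 1 (0.052), RELA-deleted replicate 1 (0.0549) or RELA-deleted replicate 2 (0.0513). Of 40 mitochondrial respiration genes 1 rose and 0 fell, and 0 changed when adjusted over the list alone (camera adjusted p = 0.406, median -0.05). The median of these genes lay between -0.06 and -0.02 with 1 library left out. At an unadjusted p under 0.05 1 was higher and 6 were lower with edgeR, and DESeq2 called 0. That gene was Cyc1, cytochrome c1 (0.11, SE 0.03), whose call was lost without control replicate 1 (0.139), control replicate 2 (0.08), RELA-deleted replicate 1 (0.158) or RELA-deleted replicate 2 (0.0561) and with DESeq2 (0.0567). Cox6a1 (-0.11), Sdhc (-0.10) and Atp5o (-0.08) did not pass, but Cox6a1 passed without control replicate 2 (adjusted p = 0.0342) or RELA-deleted replicate 3 (0.0493) and with no filter (0.0496), where 1, 2 and 2 members of the list fell.

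Immediate early and stress genes went both ways, 9 of 39 rising and 6 falling, or 11 and 10 adjusted over the list alone, with a median of 0.00 (camera adjusted p = 0.184). Jun, a subunit of the AP-1 transcription factor, rose from 39.4 ± 1.26 to 85.7 ± 2.64 CPM (log2 fold change 1.12, SE 0.04), and the related Jund rose by 0.37 (SE 0.04). The immediate early gene Ier5 fell by 0.37 (SE 0.03) and the mTOR inhibitor gene Ddit4 by 0.53 (SE 0.04) on the log2 scale.

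Markers of B-cell subsets were compared next. Follicular and immature B-cell markers had 8 of 15 members that rose and 3 that fell, or 9 and 3 adjusted over the list alone, with a median log2 change of 0.19. Tnfrsf13c, the receptor of the survival factor BAFF, rose from 371 ± 15.4 to 473 ± 10.6 CPM (0.35, SE 0.03), Cd24a by 0.31 (SE 0.03) and Lck by 0.32 (SE 0.03). The follicular marker Fcer2a (CD23) fell by 0.31 (SE 0.03), with Bmf (-0.28) and Cxcr5 (-0.09) as the other falls. The list was higher with camera (adjusted p = 7.93e-04), and the call was lost with an estimated correlation (adjusted p = 0.173). Marginal zone and B1 markers had 5 of 22 members that rose and 7 that fell, or 5 and 8 adjusted over the list alone, and their median of -0.09 and mean of 0.06 differed in sign (camera adjusted p = 0.406). Plxnd1 fell by 0.52 (SE 0.04) and Ahr by 0.17 (SE 0.03), while Zbtb32 and Spn (CD43) rose by 0.50 (SE 0.06) and 0.39 (SE 0.06). Sox5, Pdlim1 (0.28) and Plscr1 (0.22) were the other rises.

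Markers of T and NK cells were higher in the RELA-deleted libraries, from low levels. Of 25 measured members, 11 rose and 0 fell with edgeR, or 13 and 1 when adjusted over the list alone or at an unadjusted p under 0.05, with a median log2 change of 0.41. The median was 0.38, 0.31 and 0.24 with limma on log2(CPM + 0.1), log2(CPM + 0.5) and log2(CPM + 1). Cd3e and Cd3g, chains of the T-cell receptor complex, rose from 0.501 ± 0.114 to 1.39 ± 0.0468 CPM and from 0.466 ± 0.019 to 1.34 ± 0.182 CPM. The transcription factor genes Tcf7 and Tbx21 rose by 0.50 (SE 0.09) and 0.96 (SE 0.20). The camera adjusted p was 1.12e-04, and the call was lost with an estimated correlation (adjusted p = 0.0607). DESeq2 called 7 rises and 0 falls. A filter of at least 5 CPM left 3 measured members, of which 2 rose. The falls numbered 1 without control replicate 3, with no filter, no abundance trend or robust moderation and with sample weights in limma voom. Prf1 had been at -0.89 (adjusted p = 0.0548, edgeR's quasi-likelihood test) with all libraries.

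Neutrophil and granulocyte markers also were higher, with 9 of 14 rising and 1 falling, or 10 and 2 adjusted over the list alone, and a median log2 change of 0.62. S100a8 and S100a9, the calgranulins, rose from 10.5 ± 0.789 to 16.2 ± 0.973 CPM and from 13.4 ± 0.794 to 21.4 ± 2.98 CPM. The granule protein gene Ngp rose by 1.31 (SE 0.17) and the G-CSF receptor gene Csf3r by 0.60 (SE 0.08). The member that fell was Prg2 (-0.80), an eosinophil granule gene, and the falls numbered 2 without control replicate 1 and with no filter, and 0 without control replicate 2 and with DESeq2. With a filter of at least 5 CPM 4 of 5 measured members rose and 0 fell. These markers were higher with camera (adjusted p = 5.01e-06), and the call was lost with an estimated correlation (adjusted p = 0.107).

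Monocyte, macrophage and dendritic cell markers did not shift as a list (camera adjusted p = 0.521, median -0.07), with 2 of 20 rising and 3 falling, over all genes and over the list alone. The macrophage marker Emr1 (F4/80) rose from 7.54 ± 0.544 to 15.1 ± 0.8 CPM (SE 0.08 on the log2 scale) and the integrin gene Itgam rose by 0.75 (SE 0.10). Bst2, which is also an interferon response gene, fell by 0.75 (SE 0.04), Mpeg1 by 0.25 (SE 0.04) and Ly6c2 by 0.73 on the log2 scale. Erythroid and platelet markers had 4 measured members, of which Tfrc rose (0.15, SE 0.04), Car2 fell (-0.38, SE 0.08), and Alas2 (0.70) and Itga2b (0.31) did not pass. Alas2 did pass without control replicate 3 (adjusted p = 0.0483) and with sample weights in limma voom (0.048), where 2 members rose, as with no filter. Adjusted over the list alone, 2 rose and 1 fell. Tfrc lost its call without control replicate 1 (adjusted p = 0.0982), control replicate 2 (0.066), RELA-deleted replicate 1 (0.0737) or RELA-deleted replicate 3 (0.0632). None of 4 stromal and endothelial markers passed, over all genes or adjusted over the list alone, with log2 changes of -0.11 for Pecam1, -0.16 for Vwf, -0.21 for Kdr and 0.08 for Stab2 (edgeR's quasi-likelihood test, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2), while with no filter 1 of 13 fell.

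Genes that flank Rela showed no shift as a list (camera adjusted p = 0.1247, median 0.05). Of 36 measured, 5 rose and 1 fell, over all genes and adjusted over the list alone. Sipa1 rose by 0.24 (SE 0.04), Ehbp1l1 by 0.17 (SE 0.05) and Klc2 by 0.16 (SE 0.05), with Malat1 (0.28) and Sart1 (0.10) as the other rises, and Cfl1 fell by 0.10 (SE 0.03). The rises numbered 8 with total count scaling, 3 without control replicate 3, with a filter of at least 5 CPM, with no abundance trend and with sample weights in limma voom, 2 without RELA-deleted replicate 2 and with DESeq2, and 1 without RELA-deleted replicate 3. The falls numbered 0 without control replicate 1, RELA-deleted replicate 1 or RELA-deleted replicate 2, with no abundance trend and with quantile normalization in limma voom, and 2 without control replicate 2 or control replicate 3. Ehbp1l1, Klc2 and Cfl1 each lost their call in 3 of the leave-one-out fits, with adjusted p up to 0.108, 0.0992 and 0.196. Klc2 also lost it with DESeq2 (0.067), and Cfl1 with quantile normalization in limma voom (0.0765) and without an abundance trend (0.0553). Xist, the X-inactivation transcript, was present in all 6 libraries at 63102 to 80244 counts and did not differ past the threshold (0.03, SE 0.03, over all genes or the list alone), and Ddx3y, Kdm5d, Eif2s3y and Uty on the Y chromosome had 0 counts in every library, which allows up to 3 counts of each.

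**Figure D3:**
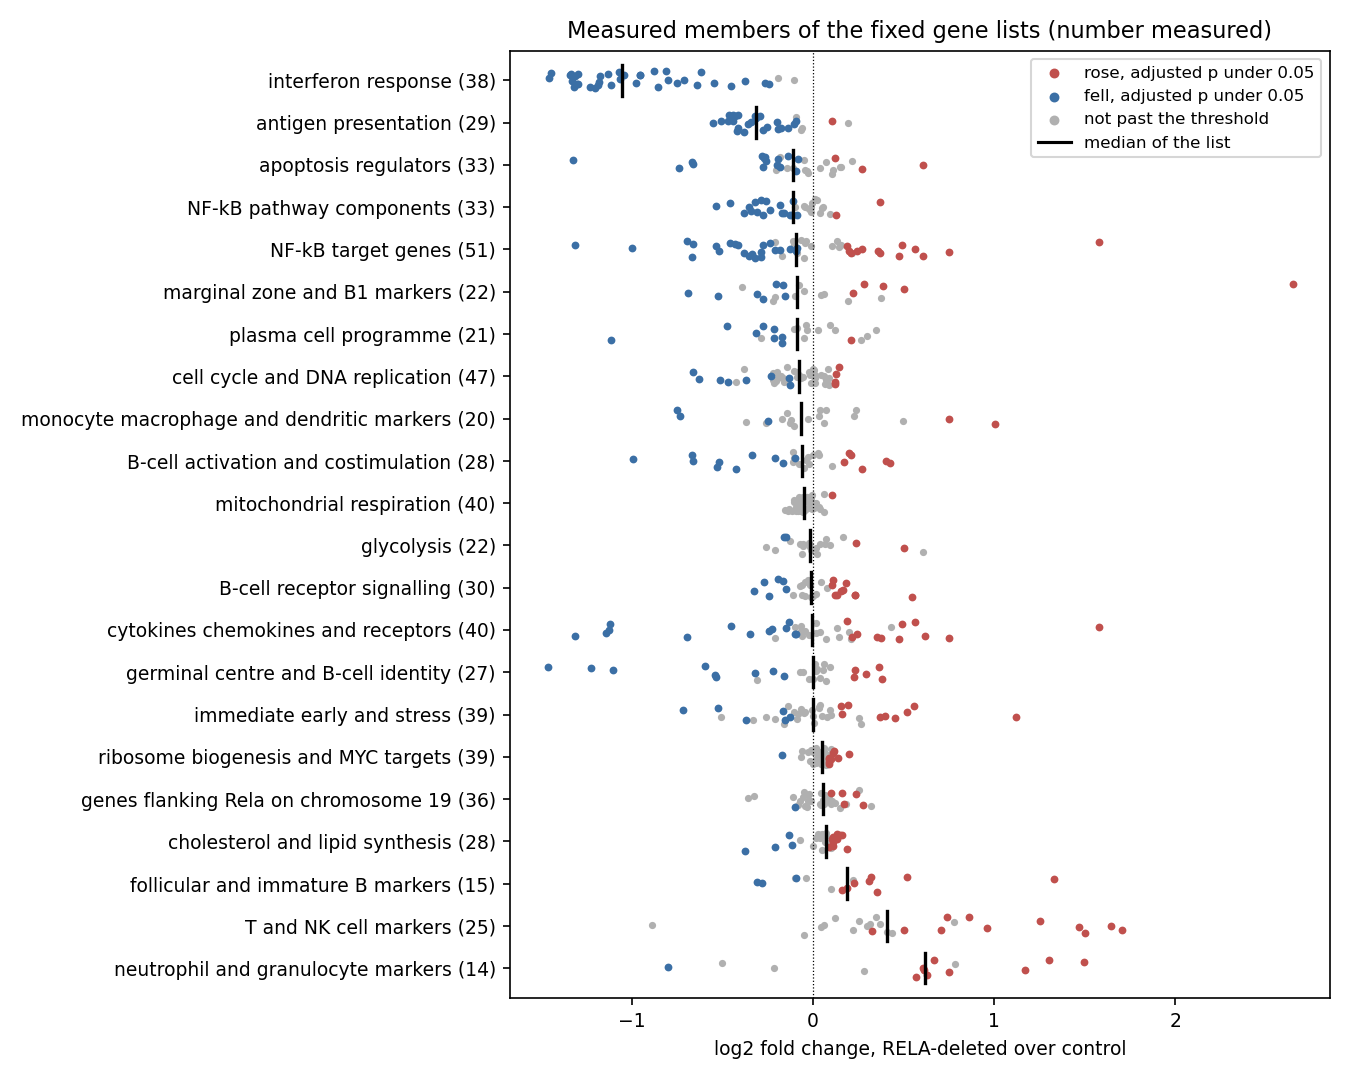
Log2 fold change (RELA-deleted over control, horizontal axis) of each measured member of the gene lists with at least 5 measured members, 1 list per line, with the number measured in parentheses, colours for members past an adjusted p of 0.05 and a black bar for the median. The interferon response list lies farthest to the left with a median of -1.05, and the neutrophil list farthest to the right with a median of 0.62.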

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

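Limma on log2(CPM + 1), scaling by total count and the tests of the lists under these were chosen after seeing the data, and the other alternatives before. Rela stayed between -2.45 and -2.35 on the log2 scale under every alternative. The number of changed genes, 1986 with all libraries, was 1342 with DESeq2 (575 rose and 767 fell) and ranged from 1344 to 2131 when 1 library was left out, with rises from 543 to 913 and falls from 794 to 1218. Leaving out a library reduces the samples tested, but without control replicate 3 the count rose to 2131. That library differed more from control replicates 1 and 2 (chi-square per degree of freedom 3.83 and 3.81) than these did from each other (1.84). The cause of the lower count with DESeq2 was not tested. Of the 1342 genes called by DESeq2, 1340 were among the 1986. Under the other alternatives at an adjusted p under 0.05 the count lay between 1777 (at least 5 CPM) and 2695 (replicate block), and 2669 genes passed at an adjusted p under 0.1. The share of rises among the calls, 44.8% with all choices kept, was 50.5% with total count scaling and 50.3% with quantile normalization in limma voom, which changes the test as well. The deviations of control and RELA-deleted libraries with the same replicate number correlated at -0.01, 0.22 and 0.23 across 7816 genes. Libraries with unlike numbers correlated at -0.28 to 0.15. Of 6 libraries, 4 correlated best with their own number, so a source of variation shared by number stays possible. The labels name no batch, and the numbers were not used to pair the samples in the main test. With the replicate block 2695 genes changed (1292 rose and 1403 fell), including all 1986.

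Of the 12 lists of genes past camera, 2 passed with an estimated correlation, which allows for members that vary together. The values that changed direction belonged to genes and lists that had not passed. With 1 library left out, Kdr ranged from -0.44 to 0.11, Stab2 from -0.25 to 0.51 and Xist from -0.017 to 0.056, all 3 turning without control replicate 3 and Stab2 also without RELA-deleted replicate 3 (-0.14). Stab2 stood at -0.062 with sample weights in limma voom, and the medians of the germinal centre and cytokine genes, close to 0, were positive in 5 and 6 settings (0.0014 to 0.0199, with 0.012 at a filter of 5 CPM, and 0.0002 to 0.0404). The median of the monocyte list was positive in 3 settings (up to 0.0139) and that of the immediate early list negative in 3 (down to -0.0198), and the erythroid median was -0.12 at the 5 CPM filter, which left 2 members. For the glycolysis genes, the test turned upward at medians of -0.014 with no filter and -0.0048 with total count scaling, and also without control replicate 3 or RELA-deleted replicate 2, within a range of -0.030 to 0.0053 over the left-out libraries. The cause was not tested. Across the named genes and alternatives, 2123 values kept direction and side of the threshold, 40 lost the call and 8 gained it, and for the lists the numbers were 370, 18 and 2. The named genes were chosen for small p or large changes, so these numbers do not describe all called genes. Of all genes called in the main test, 65.9% were also called without RELA-deleted replicate 1, the lowest share with 1 library left out. The highest such share was 86.7%, without control replicate 3, and DESeq2 shared 67.5%. The camera test of the lists was not rerun with DESeq2, no abundance trend or robust moderation, which give camera no other input. With the replicate block, the cell cycle list no longer passed camera (adjusted p = 0.0719). That block also called Cox6a1 (0.0193), Sdhc (0.0371) and Atp5o (0.0396), with 7 falls among the mitochondrial genes. The 40 lost calls came from 12 genes, some counted under several settings. Of these calls, 25 were on 7 genes at 50 CPM or more in the control libraries, so low counts alone do not explain all of them.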

Other observations

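The gene families and single genes in this paragraph and all tests below except the splits of the libraries were chosen only after the results were seen. Families related to the interferon response but largely outside its list were also lower in the RELA-deleted libraries. Of 8 Schlafen genes 5 fell and 0 rose, led by Slfn5 (log2 fold change -1.42, SE 0.06) and Slfn8 (-0.71, SE 0.05). Of 7 genes of the Trim30, Trim12 and Trim34 cluster 6 fell, with Trim30d at -0.98 (SE 0.04). Of 8 PYHIN genes, which include sensors of cytosolic DNA, 5 fell, with Pydc3 at -1.15 (SE 0.06) and Mndal at -0.67 (SE 0.03). Of 15 guanylate-binding and immunity-related GTPases 10 fell, among them Gbp9 (-0.62, SE 0.04) and Irgm1 (-0.45, SE 0.04). Members of each family share sequence, so the values of single members are uncertain. Axl, a receptor kinase of the same family as Tyro3, fell from 180 ± 2.71 to 89.5 ± 1.66 CPM, and the galectin gene Lgals9 from 132 ± 4.40 to 67.9 ± 2.48 CPM (SD, n = 3).

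Known p53 target genes were lower as well. Of 40 measured, 21 fell and 1 rose, with a median log2 change of -0.20. Psrc1 (-1.38, SE 0.08) and Phlda3 (-1.39, SE 0.10), which with Tnfrsf10b, Bbc3 and Cdkn1a drew attention to the group, had the largest falls. Further members were Gtse1 (-0.90, SE 0.07), Ccng1 (-0.52, SE 0.04) and Zmat3 (-0.52, SE 0.05). Of 9 Fos, Jun and related genes, Jun and Jund rose and the other 7 did not pass the test.

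The fall of the interferon response genes (36 of 38) was weighed against 4 explanations. If myeloid or dendritic cells held the interferon response transcripts, their loss would lower their other markers by a like amount. The 19 such markers outside the interferon list had a median log2 change of -0.025 (95% bootstrap interval over markers -0.14 to 0.07). The 9 of them under 5 CPM in the control libraries, a limit set after seeing the data, gave 0.041 (interval -0.37 to 0.50). These values argue against a loss of these cells as a whole, but the intervals take markers as independent although they come from the same libraries. A median over all these markers could miss the loss of only 1 kind of cell, which was not tested. Loss of cells that act on the B cells without holding these transcripts need not move this median and stays open. A single control library with a high response is argued against by 36 falls or more whichever library was left out. Lower transcript of the type I interferon receptor is argued against too, since the lower of the changes of Ifnar1 and Ifnar2 was 0.056. Less type I interferon made in the culture stays open, as the 13 Ifna and Ifnb1 genes gave 2 counts in the control libraries and 0 in the RELA-deleted libraries (exact binomial p = 0.236), too few to decide. A lower interferon response in RELA-deleted B cells may follow from the deletion, as a hypothesis, and litter, cage or handling of the mice could not be tested because the labels do not name them.

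T-cell and neutrophil markers were higher in the RELA-deleted libraries although B cells had been purified with magnetic beads, a step that should remove both. A lower share of B cells alone would raise the markers of every other cell type alike, and it stays open, as over the 19 neutrophil, myeloid and dendritic markers under 5 CPM in the control libraries the neutrophil median exceeded the other by 0.64 on the log2 scale, with a 95% bootstrap interval from -0.0060 to 1.17, while over all 33 the excess was 0.65 (interval 0.31 to 0.89) but includes markers whose higher baseline could hide a small rise. More T cells (median 0.41, interval 0.30 to 0.78, 25 genes), more neutrophils (median 0.62, interval 0.28 to 0.78, 14 genes) and higher expression in the B cells themselves cannot be told apart by these medians, which restate the pattern. The most abundant markers were low, Il1r2 at 20.04 CPM and Il7r at 15.7 CPM in the control libraries and S100a9 at 13.4 and 21.4 CPM in the control and RELA-deleted libraries, and the myeloid gene Lyz2 was at 14.5 ± 2.66 and 16.9 ± 1.24 CPM. At least 5 CPM in the control libraries was reached by 3 of 25 T and NK markers, 4 of 14 neutrophil markers and 11 of 20 myeloid and dendritic markers, some of which B cells may express, and 1, 0 and 2 members stand in another list.

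The list of p53 target genes was written after some members had been seen to fall. Its 26 members that stood in no earlier list were tested alone, with Psrc1 and Phlda3 left out. They were lower with camera (p = 5.31e-07, and p = 0.00497 with an estimated correlation), with 10 falls and 0 rises. The list was written with the results of these libraries at hand, and the 26 include Gtse1, Ccng1 and Zmat3, so this was no independent test. Trp53 itself changed by -0.19 on the log2 scale (SE 0.04, adjusted p = 7.86e-04, edgeR's quasi-likelihood test), which is consistent with less p53 but is small beside the falls of Psrc1 and Phlda3. Lower p53 activity in the RELA-deleted cells is a hypothesis, and differences in the handling or survival of the cells between groups were not tested and stay open.

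The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1986 changed genes, and the highest of the other splits gave 0, so 1 split gave as many. Each other split put libraries of both groups on both sides, where any difference between the groups adds to the spread within a side. Few calls were therefore likely in those splits whatever made the groups differ, and these counts tell nothing about the cause.

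Rpl11, a ribosomal protein gene with processed pseudogenes, was at 373, 293 and 298 counts in the control libraries and at 382, 1506 and 1459 counts in the RELA-deleted libraries, a 4.31-fold range of CPM within the group.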
